A study of Oryza sativa with 6 samples.

How the data were processed

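Total RNA from 6 samples, 3 wild-type and 3 OsCAld5H1-knockout, was labelled with Cy3 from 0.1 µg and hybridised to a 1-colour Agilent rice array, per the labels' protocols. Plants were grown at 27 °C with a 12 h photoperiod, per the labels. The deposited scanner files hold spot intensity, background-subtracted and detrended within each array by Agilent Feature Extraction 12.0.3.1, per the file headers and the submitters' processing notes, and not scaled between arrays. They also hold median spot and local background intensity and 0/1 flags. The deposited value table of the authors holds intensity on a linear scale: each column equals the processed signal of that array times 1 constant (1.72, 1.59, 1.55, 1.63, 1.51 and 1.60 for wild-type and knockout replicates 1 to 3), which brings the mean trimmed by 2% at each end to 2501. Its medians were 379, 379, 376, 388, 385 and 387. It is uncentred, and as intensity it has no direction to settle; how the constants were chosen is not given in the sources used here.

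The log2 of the processed signal minus its 75th percentile on the array was used. Of 43734 gene spots, 590 of the design's own control probes and all spots flagged as outliers (5 to 9 per array) were left out, and spots of a probe were averaged, giving 42418 probes. A probe counted as well above background where over 0.5 of its spots were, and was tested where this held on all 3 arrays of at least 1 genotype, with at least 2 measured arrays in each. This left 32135 probes. limma 3.58.1 in R 4.3.3 was fitted with genotype as the one term, with a two-sided moderated test, and adjusted p under 0.05 after Benjamini-Hochberg was the threshold. Where a locus had several probes, the brightest over the 6 arrays stood for it. A probe not well above background in 1 genotype has only a bound: the mean of the bright genotype was set against the mean, per array, of the higher of the dim probe's own signal and the lowest signal well above background, provided every probe of the locus was dim.

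Gene lists were tested with camera at a preset correlation of 0.01, for lists with at least 3 tested loci. Of the lists fixed before the data were examined, 5 held loci and 17 were defined by product name. The files and the reference table hold no product names for these identifiers, so the latter could not be filled; 12 lists of loci were then written by hand, before expression values were compared. Gene names of listed loci come from prior knowledge of rice nomenclature, not from the files. Of 173 listed loci, 104 names occurred in the reference table (assembly ASM3414082v1); 100 of these lay on the chromosome that the locus identifier gives, and all 468 pairs of them on 1 chromosome ran in the same order as their identifiers. The 4 others were C3H1, C3H2, CYP76M7 and PRR95, whose names the table gives on another chromosome; The table gives PRR95 on the chromosome of the locus listed as PRR59, so neither is named singly. In the table OsC3H1 and OsC3H2 belong to another numbered series of genes; C3H1 and C3H2 stand here for the listed loci Os05g0494000 and Os10g0196000, without support from the table. The names of the other listed loci do not occur in the table and were not checked; among them are CAld5H1 and CAld5H2, every PAL and C4H gene, CAldOMT1, the caffeoyl-CoA methyltransferase and cinnamoyl-CoA reductase loci, the secondary wall transcription factors, most photosynthesis genes, DFR and IPS1.

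The rule for named genes took, among loci with a product name, past the threshold and without overlap between the genotypes' arrays, the 12 largest changes per direction in genes bright on all 6 arrays and the 4 largest bounds per direction. It added every tested core monolignol gene and the 3 largest changes of any list that passed. Without product names its first parts could not be used; 1 identifier each, called members of the other lists and examples from those lists were chosen after their values were seen. The scripts were tested on simulated data of the 32135 tested probes, in which 100 probes each were changed by known amounts: 34% of 2-fold and 78% of 4-fold changes were recovered, 1 of 113 calls was false, and 0 probes were called with no change. The simulated noise was independent between probes, had the same SD in both genotypes and held no slide or array effect. These rates therefore test the scripts and do not carry over to the real calls.

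Alternatives covered normexp (offset 50) with quantile normalisation, quantile normalisation alone, the authors' values, no filter and a stricter filter on dim probes, keeping outlier spots, the replicate number as a block, limma-trend, array weights, other thresholds, leaving out each array, and for lists an estimated correlation, fry and the mean of all probes. The planned mean spot signal is not a column of the files, so normexp used the median. Slide could not enter as a block because each slide holds 1 genotype. With an estimated correlation, camera takes its p from the 4 residual degrees of freedom. Its p values therefore differ from the preset ones by more than the correlation.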

Results

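The internode transcriptome of rice was compared between wild-type plants of the cultivar Nipponbare and a line in which OsCAld5H1 had been knocked out. OsCAld5H1 encodes coniferaldehyde 5-hydroxylase, the enzyme that opens the syringyl branch of lignin synthesis. Each genotype was represented by 3 biological replicates, and 1 array was hybridised per replicate. The tissue was the middle of the second internode from the top, taken at heading. The knockout plants were of the T2 generation of a single edited line. Between 74.3% and 78.3% of the gene spots on each array were well above background, and no gene spot was saturated. The number of arrays limits the precision of every value. The 3 wild-type arrays shared 1 slide and the 3 knockout arrays another, so slide and genotype cannot be told apart.

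The first question was whether the transcript of the targeted gene differed. The probe for OsCAld5H1 (locus Os10g0512400, chromosome 10) lies in the coding sequence and 3′ untranslated region, and the position of the edit is not given in the sources used here, so its level does not test the edit itself. Relative to the 75th percentile of each array, its log2 signal was -0.54, -0.52 and -0.05 in wild-type replicates 1, 2 and 3. It was -4.00, -1.78 and -1.23 in knockout replicates 1, 2 and 3. Every knockout array was thus below every wild-type array. The difference was -1.97 ± 0.70 on the log2 scale (SE, n = 3 per genotype), and limma's adjusted p was 0.205, so it did not pass the threshold of 0.05. Knockout replicate 1 set much of its size. Without that array the difference was -1.14, with an adjusted p of 0.0643.

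**Figure D1:**
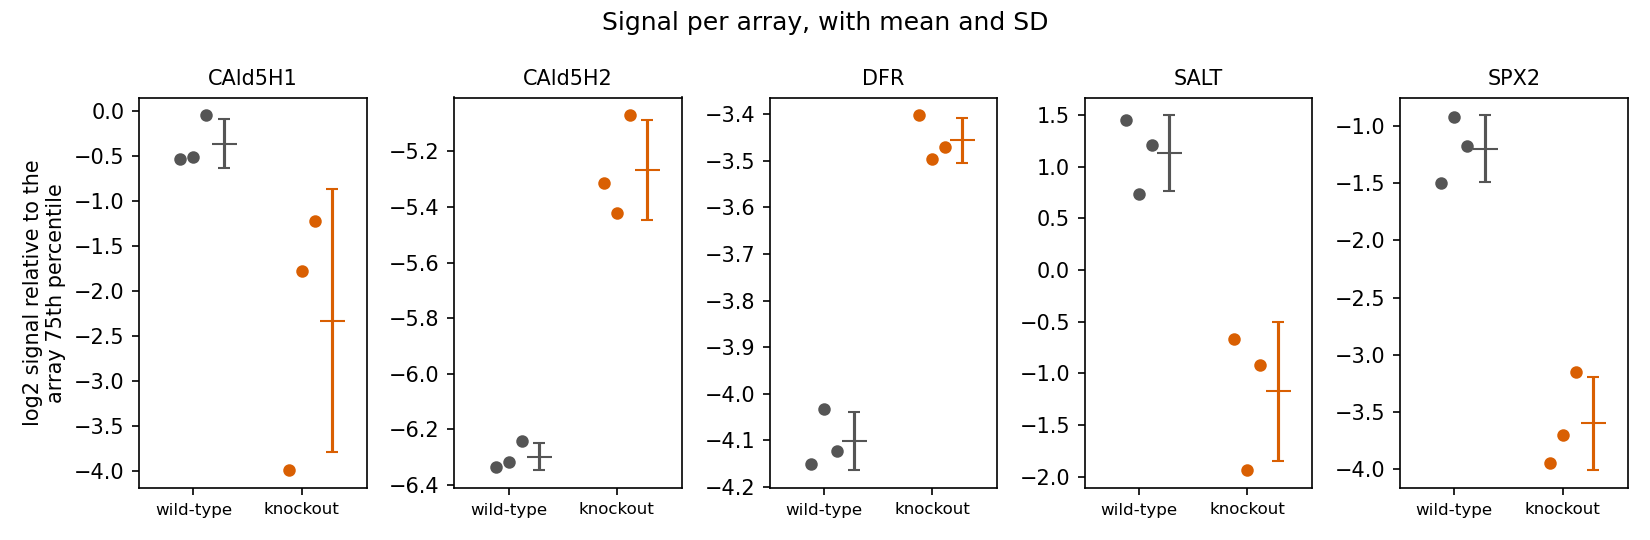
Each panel plots the log2 signal relative to the array's 75th percentile (vertical axis) for 1 gene, in 3 wild-type and 3 knockout arrays (points), with the mean and SD of each genotype beside them; the vertical scales differ between panels. Means were -0.37 and -2.33 for CAld5H1, -6.30 and -5.27 for CAld5H2, -4.10 and -3.46 for DFR, 1.13 and -1.17 for SALT, and -1.20 and -3.60 for SPX2, in wild-type and knockout arrays in that order.

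The second question was which transcripts differed between the genotypes as a whole. In the knockout arrays, 601 probes rose and 416 fell, together 3.16% of the 32135 probes tested by limma with Benjamini-Hochberg adjustment. At 1 probe per locus, 474 of 21800 loci rose and 270 fell. The largest measured rise was at locus Os01g0108500, whose log2 signal went from -5.41 ± 0.17 to 0.35 ± 0.15 (SD, n = 3 each), a 54.3-fold difference. Locus Os03g0629800 was not well above background in any wild-type array and was, at this scaling, at least 282-fold higher in the knockout arrays. Os01g0108500 and Os03g0629800 have 1 probe each on the array, so no other probe checks these rises. The largest measured fall was at Os03g0102700, from 0.78 ± 0.41 to -3.14 ± 1.29, a 15.1-fold difference, and the other probe of that locus differed by -3.71. Locus Os02g0658100 was not well above background in any knockout array and was, at this scaling, at least 18.7-fold lower there. With normexp, whose offset shrinks differences of dim probes, the log2 differences were 4.38 for Os01g0108500, 5.36 for Os03g0629800 and -1.998 for Os02g0658100, so both bounds hold only for the scaling used. The files do not pair these identifiers with gene names, and the 4 were chosen by size after their values were seen. The call of Os03g0102700 ended without a filter on dim probes (adjusted p 0.0554) and when any single array but knockout replicate 3 was left out (0.134, 0.0990 and 0.139 without wild-type replicates 1, 2 and 3, 0.0597 and 0.0795 without knockout replicates 1 and 2). That of Os02g0658100 ended with normexp (0.0580) and without wild-type replicate 1 (0.0743) or knockout replicate 2 (0.0509). The probe count depended on single arrays: it was 145, 197 and 136 without wild-type replicates 1, 2 and 3, and 1505, 245 and 1261 without knockout replicates 1, 2 and 3. The split between directions also moved with scaling, to 454 rises and 492 falls after normexp and quantile normalisation.

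The arrays of the genotypes differed in 2 further measured respects. The knockout arrays varied more, with a median SD of 0.253 per probe against 0.127 in wild-type, and knockout replicate 1 stood apart. Across probes, which are not independent replicates, knockout replicates 2 and 3 correlated at 0.984, and replicate 1 with them at 0.972 and 0.968. Knockout replicate 3 correlated with the wild-type arrays at 0.972, 0.981 and 0.976. Over 446 loci with a probe at each end of the transcript, the median log2 excess of 3′ over 5′ signal was 1.80 ± 0.01 in wild-type and 1.90 ± 0.01 in knockout arrays (SD, n = 3 each). An exact two-sided permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow.

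The third question was whether the rest of the lignin pathway moved with the genotype. Of 35 core monolignol loci, 29 were tested; 1 rose, none fell and 28 did not pass (7 of the 29 had an unadjusted p under 0.05). The one that rose was CAld5H2 (Os03g0112900), listed as a homologue of the targeted gene and dim in both genotypes. Its log2 signal was -6.30 ± 0.05 in wild-type and -5.27 ± 0.18 in knockout arrays (SD, n = 3 each), a 2.04-fold difference with a limma adjusted p of 0.0190. Its locus has 1 probe on the array. Control probes of the array, which are outside the genes compared, also differed. POsControl0021, POsControl0001 and PZmControl0003 were higher in the knockout arrays by 1.56, 0.54 and 0.31, and POsControl0005 differed by -0.52. Whether nonspecific signal raised CAld5H2 was not tested. The call ended with normexp (adjusted p 0.0998), with a replicate block (0.0531), and without wild-type replicate 1 (0.0962), 2 (0.0881) or 3 (0.0977). Adjusted over the list alone, 2 members passed, the other being C4H2, a cinnamate 4-hydroxylase (log2 difference 1.01 ± 0.21 SE; adjusted p over all probes 0.0655). With normexp these differences were 0.33 for CAld5H2 and 0.39 for C4H2. By camera, the list as a set had an adjusted p of 0.268. Its median difference was 0.08 and its mean -0.07, so these differed in sign, and the set test pointed upward.

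Several of the brightest enzymes of the pathway differed little, and the sign of PAL2, PAL4, PAL5, HCT1 and the dimmer 4CL5 turned with the scaling. The log2 differences were 0.01 for PAL1, -0.05 for PAL2 and -0.01 for PAL5, which are phenylalanine ammonia-lyases at the entry of the pathway. For CAldOMT1, the methyltransferase acting after OsCAld5H1, the difference was 0.15, with a 95% interval from -0.11 to 0.40. It was 0.015 with quantile normalisation and 0.018 with normexp. For CAD2, the main cinnamyl alcohol dehydrogenase, it was 0.08, and for HCT1 and HCT2, the hydroxycinnamoyltransferases, -0.11 and 0.24. The cinnamoyl-CoA reductases at Os08g0441500 and Os09g0419200 differed by -0.20 and 0.08. Other tested probes of these loci did not all match. They ran from -0.29 to -0.26 for HCT1, from -0.22 to 0.44 for Os08g0441500 and from 0.02 to 0.17 for Os09g0419200. For PAL1 they ran from -0.11 to 0.01, for PAL2 from -0.04 to 0.16, for CAldOMT1 from -0.06 to -0.02 and for CAD2 from -0.03 to 0.09. Those of PAL5 and HCT2 were at -0.12 and 0.72, and none of these other probes was called. Among the other genes with an unadjusted p under 0.05 that did not pass, the differences were 0.47 for C4H1, 0.43 for 4CL3, 0.33 for the caffeoyl-CoA methyltransferase at Os08g0498400 and 0.32 for Os05g0494000, listed as C3H1, a name that the reference table gives to a gene on another chromosome. The other tested probe was at 0.18 for C4H1 and at 0.12 for Os08g0498400. Differences were larger but imprecise for the 4-coumarate:CoA ligase 4CL1 (-0.90 ± 0.37 SE) and for C4H3 and C4H4 (-1.26 ± 0.99 and -1.45 ± 0.98 SE). The remaining tested members differed by 0.12 for PAL4, -0.49 for PAL7, 0.33 for PAL9, 0.01 for 4CL4, 0.0027 for 4CL5 and -0.10 for the locus listed as C3H2. Those for the caffeoyl-CoA methyltransferases at Os06g0165800, Os08g0498100, Os08g0498600 and Os09g0481400 were 0.26, 0.16, -0.65 and 0.09. The probe at Os08g0498600 was well above background on 2 of 3 knockout arrays. The other tested probe differed by -0.37 for PAL4 and by 0.0043 for 4CL4. PAL3, PAL6, PAL8, 4CL2, CAld5H3 and the reductase at Os02g0808800 were too dim to be tested.

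**Figure D2:**
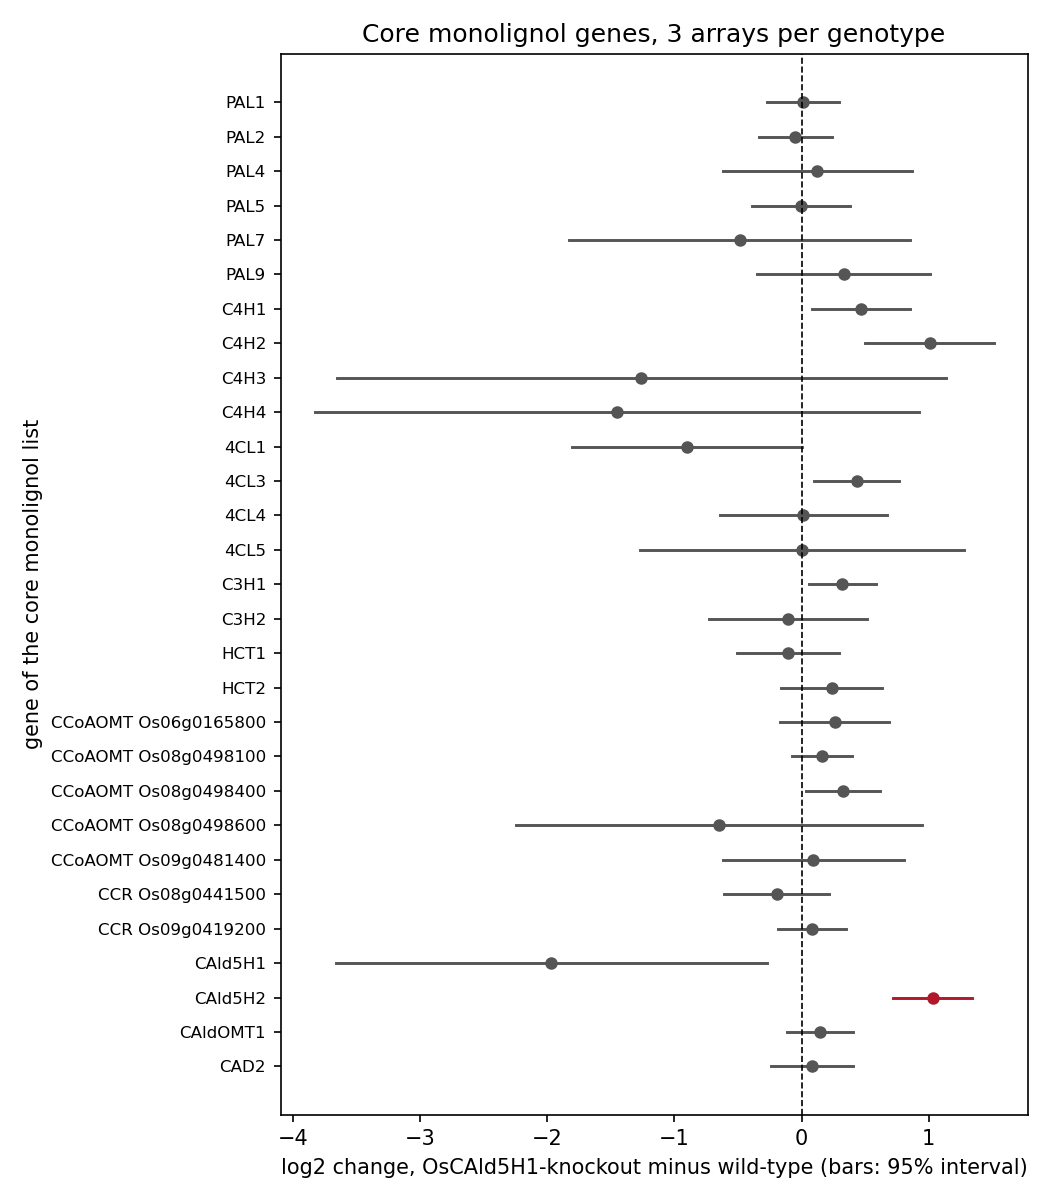
The horizontal axis gives the log2 difference, knockout minus wild-type, for the 29 tested core monolignol genes (vertical axis); points are the fitted differences and bars their 95% intervals from limma, not adjusted for the number of genes. CAld5H2, in red, was the one gene past the threshold, at 1.03; CAld5H1 lay at -1.97.

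Genes that build the polysaccharide wall did not pass the test singly. All 5 primary wall cellulose synthases were higher in the knockout, with CESA5 at 0.73 ± 0.19 and CESA8 at 0.35 ± 0.12 (log2 difference, SE). None passed over all probes (limma; 2 had an unadjusted p under 0.05) and 1, CESA5, passed adjusted over the list alone. The adjusted p of the set was 0.0890; the set passed with normexp (0.0368), without a filter (0.0457), and without wild-type replicate 3 (0.0189) or knockout replicate 1 (0.0224). With an estimated correlation over all 6 arrays it did not (p = 0.189, adjusted p = 0.772). None of 7 tested secondary wall genes passed on either basis (0 with an unadjusted p under 0.05), with differences from -0.38 for CESA9 to 0.86 for IRX9, CESA4 at 0.12 and CESA7 at 0.02. Other tested probes ran from -0.85 to 0.05 for CESA4, and that of CESA7 was at 0.19. Relative to the wild-type mean, the median of these genes was -0.50 in knockout replicate 1 and 0.33 and 0.34 in replicates 2 and 3. That set had an adjusted p of 0.762, and 0.0291 without knockout replicate 1; with an estimated correlation over all 6 arrays, p was 0.841. None of 6 tested secondary wall transcription factors passed on either basis at its brightest probe (1 with an unadjusted p under 0.05; set adjusted p 0.762). The other tested probe of SWN1 rose, by 1.05, against 0.08 at the brightest. Of 8 circadian clock genes, 7 were lower (6 with normexp), with GI at -0.96 ± 0.25 and PRR73 at -1.16 ± 0.32 (log2 difference, SE). Some of the 7 differed little, with LHY at -0.06 and ELF3 at -0.02. The other tested probes of LHY were higher, by 0.07 to 0.11. None of the 8 genes passed over all probes (4 with an unadjusted p under 0.05), and 3 passed adjusted over the list alone. The set had an adjusted p of 0.116, and passed without a filter (0.0396), but not with an estimated correlation (p = 0.0786). By fry, which asks whether the genes move on balance 1 way and does not compare them with other genes, its adjusted p was 0.0327.

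Further lists were written once the files showed no product names, but before any expression value was compared. The 5 phosphate starvation genes were all lower in the knockout under every scaling tried, and theirs was the one set past the threshold of the 15 tested (camera adjusted p 0.00818). With a correlation estimated from the data no set passed, and this call was lost (p = 0.0243, adjusted p = 0.365), as it was with the stricter filter (adjusted p 0.0767). The estimate for this set, -0.173, was below the preset 0.01, so correlation among its genes did not end the call. That setting takes its p from 4 residual degrees of freedom, which raises it. When the 6 arrays were regrouped in the other ways possible, between 1 and 5 sets passed each time. SPX2, which encodes a phosphate-sensing SPX protein, fell by 2.40 ± 0.25 (log2, SE; 5.29-fold, limma adjusted p 0.0123). SPX3 and IPS1 differed by -0.94 and -0.81 and did not pass over all probes; adjusted over the list alone, SPX2 and IPS1 passed. SPX3 was well above background on 1 of 3 knockout arrays and IPS1 on 2 of 3, so the stricter filter left out SPX3 and this probe of IPS1. With normexp they differed by -0.13 and -0.20, SPX2 by -2.02, and the median of the list went from -0.81 to -0.20.

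Among the remaining lists, 2 genes passed over all probes. SALT, a jacalin-related lectin induced by salt, fell by 2.31 ± 0.37 (log2, SE; 4.95-fold, limma adjusted p 0.0320), and all 4 other tested probes of its locus also fell. DFR, a dihydroflavonol reductase, rose by 0.65 ± 0.10 (1.56-fold, adjusted p 0.0306), while the other 7 tested flavonoid genes did not pass and were lower (6 of them with quantile normalisation). DFR was dim, at -4.10 in wild-type arrays, and had no other tested probe. Whether nonspecific signal raised it was not tested. The DFR and SALT calls ended when any single array but knockout replicate 1 was left out. Adjusted p values were then 0.148, 0.121 and 0.163 for DFR and 0.126, 0.0864 and 0.135 for SALT without wild-type replicates 1, 2 and 3, and 0.0813 and 0.0505 for DFR and 0.0523 and 0.0515 for SALT without knockout replicates 2 and 3. Both calls also ended without a filter (0.0631 and 0.0535), and that of DFR with limma-trend (0.0536) and a replicate block (0.116). The SPX2 call ended without wild-type replicate 2 (0.0526), wild-type replicate 3 (0.0668) or knockout replicate 2 (0.0534). Markers of green tissue did not pass: 17 of 20 photosynthesis genes were lower (16 with either quantile scaling), with a median of -0.26 (set adjusted p 0.193). That set passed without wild-type replicate 2 (0.00132) or knockout replicate 2 (0.0198); with an estimated correlation over all 6 arrays, p was 0.627 and adjusted p 0.855. The sets for heat shock, jasmonate response, expansins, dividing cells, cinnamyl alcohol dehydrogenases, flavonoids, sugar transport and pathogenesis-related proteins had adjusted p values from 0.193 to 0.895. Without knockout replicate 1, those for cinnamyl alcohol dehydrogenases and jasmonate response passed (0.0291 each), and without a filter those for jasmonate response (0.0396) and dividing cells (0.0342). With an estimated correlation over all 6 arrays, p was 0.349, 0.544 and 0.370 for these in the same order. Adjusted over the list alone, 1 member passed in each of the heat shock (HSP17.9A, -0.81), cinnamyl alcohol dehydrogenase (CAD3, 0.52), flavonoid (DFR) and dehydration (SALT) lists. Of the diterpenoid phytoalexin genes 0 of 9 were bright enough to test, and 2 of 7 dehydration genes were.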

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

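Of the tests in this part, the share of risen probes above the control probes and the splits counted for gene sets were fixed before their results were seen; the 5′ probe, single-probe, spike-in and probe-count split tests were chosen after. Control probes printed by the array's designers are left out of the comparisons of genes, and serve below only as a level for other probes. Of the 4 bright enough to test, 3 were higher in every knockout array than in any wild-type array: POsControl0021 by 1.56, POsControl0001 by 0.54 and PZmControl0003 by 0.31 on the log2 scale. The other, POsControl0005, differed by -0.52 (adjusted p 0.146). The 3 are given because they are a signal outside the genes compared.

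The first pattern concerns which probes rose: among called probes at cDNA 3′ ends 327 rose and 306 fell, while outside them 274 rose (13 at 5′ ends, 22 to microRNA hairpins and 239 others, against 13, 4 and 93 that fell). After normexp and quantile normalisation 454 of all called probes rose and 492 fell. Whether the excess outside 3′ ends remains there was not tested. More nonspecific hybridisation on the knockout slide is a candidate explanation, and 20.4% of the 274 lay above the brightest control probe (95% exact binomial interval 15.8% to 25.7%). The limit set beforehand was under 25%, which the interval spans, and the level rests on 1 probe, POsControl0021, at -2.18 in the knockout arrays after its own rise of 1.56, so the explanation stays open. Median levels of all tested probes at 5′ ends, to microRNA hairpins and in the other class were -2.43, -5.13 and -2.64, below that control. A low share is thus likely whatever the cause, and no share over all such probes was taken. A 3′ shift of the labelled RNA would favour 3′ ends. The position in the transcript of the 239 others was not established, so it cannot be told whether such a shift bears on them. Of called 3′ probes 51.7% rose, and of 26 called 5′ probes 50%, the latter too few to measure such a shift. An effect of genotype cannot be told apart from nonspecific hybridisation, because genotype and slide coincide.

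The second pattern is signal in 1 genotype only: 123 probes were well above background in every knockout and no wild-type array, and 80 the reverse. They lay at 112 and 70 loci, of which 18 and 33 had another probe, so most knockout-only loci could not be checked. The spike-in RNAs, whose largest difference among 8 was 0.105, argue against a slide-wide difference in labelling. An artefact of single probes stays open for both, less so for the latter: the other probes of the knockout-only loci had a median change of 0.51 in the same direction over 18 loci, 9 of them above 0.5; those of the wild-type-only loci had 1.37 over 33, 24 of them (72.7%) above 0.5, which goes against it for most of these but falls short of the 75% set as the limit. A first calculation, replaced after its result was seen because it left out other probes that were themselves bright in that genotype only, gave 0.43 over 17 loci and 1.15 over 27. Loss of OsCAld5H1 and any other difference of the single edited line were not separated by the design.

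The 10 splits of the 6 arrays into equal groups are too few for a share under 0.05. Of these, 1, the real one, gave 1017 called probes, and the highest of the others gave 0. Each of the others mixes the genotypes, so a difference of genotype or slide enters its residual variance and lowers its count. The 0 is therefore no reference for 1017. For the set tests, 10 of the 10 gave at least the 1 set of the real split, and the highest of the others gave 5, several times the real count. That points to a structure of the samples or to genes correlated within lists, which were not separated. Estimated correlations ranged from -0.173, for the phosphate starvation set that passed, to 0.865 for expansins, against the preset 0.01.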

How the results depend on the processing

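The OsCAld5H1 difference was negative and not past the threshold under every alternative that gave it, from -2.52 to -1.14 (adjusted p 0.0643 to 0.464). The probe count, 1017, moved by over 1.5 times without a filter on dim probes (645), with a 2-fold limit (655), at adjusted p under 0.01 (127), and, chosen after seeing the data, at cDNA 3′ ends only (502). A stricter limit or fewer probes set the last 3 of these; for 645 the cause was not tested. Leaving out 1 array gave 136 to 1505. The labels do not state that replicate numbers pair the arrays. Same-number deviations correlated at 0.41, -0.17 and 0.16, and 2 of 6 arrays correlated best with their own number, which does not settle whether a pairing exists. With the replicate block 458 probes were called. The number of sets past the threshold, 1, became 2 with normexp, 5 without a filter, 0 with the stricter filter, 0 with an estimated correlation and, chosen after seeing the data, 0 over the earlier lists alone, and ranged from 1 to 5 with an array left out. By fry, which asks another question and compares no set with other genes, 2 sets passed. The phosphate starvation set lost its call with the stricter filter (adjusted p 0.0767) and the estimated correlation (0.365). Its estimate, -0.173, was below the preset 0.01, so correlation among its genes did not end the call. That setting leaves 4 residual degrees of freedom. The stricter filter left out SPX3 and the brightest probe of IPS1, which were well above background on 1 and 2 of 3 knockout arrays. The call of the set thus depended on probes near background. The slide block was not run, since each slide holds 1 genotype. Over 346 values of named genes under other settings, 328 kept their direction and side of the threshold, 8 lost the call and 10 changed sign. With 1 array left out these were 192, 23 and 19 of 234. Only called genes could lose a call: CAld5H2, DFR, SALT, SPX2 and the loci chosen by size. Most of the values come from genes that never passed, so these shares do not measure how stable the calls were. Signal near background limits the dim genes, whose differences shrank with normexp: CAld5H2 to 0.33 (adjusted p 0.0998), C4H2 to 0.39, SPX3 to -0.13, IPS1 to -0.20 and Os02g0658100 to -1.998.

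The changes of sign were all in differences that did not pass. With normexp they were PAL2 (0.062), PAL4 (-0.093), PAL5 (0.0054) and HCT1 (0.021); with quantile normalisation PAL2 (0.025), PAL5 (0.0096) and 4CL5 (-0.027); with the authors' values 4CL5 (-0.0064); and with array weights PAL1 (-0.0065) and PAL4 (-0.040). With 1 array left out, differences ranged from -0.056 to 0.069 for PAL1, -0.130 to 0.015 for PAL2, -0.212 to 0.312 for PAL4, -0.150 to 0.083 for PAL5, -0.225 to 0.261 for 4CL4, -0.546 to 0.548 for 4CL5, -0.258 to 0.124 for C3H2, -0.248 to 0.0066 for HCT1 and -0.072 to 0.417 for the CCoAOMT at Os09g0481400. The set of secondary wall transcription factors turned upward without a filter (adjusted p 0.990), and that of pathogenesis-related proteins downward with array weights (0.887). With 1 array left out, set directions also turned in some of the fits. Over all such fits, turned or not, adjusted p ran from 0.0291 to 0.979 for secondary wall cellulose and xylan. It was 0.550 to 0.999 for secondary wall transcription factors, 0.248 to 0.999 for pathogenesis-related proteins and 0.799 to 0.964 for sugar transport. The 0.0291 came without knockout replicate 1, with medians of 0.33 and 0.34 in the knockout arrays left, upward as in the main fit. The cause was not tested.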

Other observations

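The array carries probes to microRNA hairpins, which the files name, and these were singled out after their values were seen. Of 112 tested, 22 rose and 4 fell, or 23.2% called against 3.09% of other probes. The 22 are among the 274 risen probes above, for which nonspecific hybridisation on the knockout slide stays open. Of 6 tested mature-sequence probes of miR160, a family that targets auxin response factors, 5 rose by 1.06 to 1.26 on the log2 scale; the family's mature sequences are near-identical, so these are not independent. All 5 tested probes of miR399, a family induced by phosphate starvation, were higher (0.33 to 1.19) and 2 of them rose, whereas the phosphate starvation genes were lower. Of those 5 genes only SPX2 passed singly over all probes, and the call of their set was lost in some settings. Both probes of miR408 rose (0.96 and 0.84), and both probes of miR167h fell (-1.32 and -1.38). Both probes of miR171c also fell; they were well above background on 3 of 3 wild-type and 0 of 3 knockout arrays, so no size is given. These probes are dim, with a median level of -5.13, and labelling of total RNA for messenger RNA does not measure mature microRNAs.

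Called loci also lay beside each other. The placement test was chosen after the pattern was seen, and the test without shared sequence before its result was. There were 33 neighbouring pairs of tested loci called in the same direction, against a median of 13 in 2000 random placements (permutation p = 0.0005, the smallest they can give), which argues against chance placement. A run of 8 tested loci on chromosome 10 all fell. The 6 that were well above background on all knockout arrays differed by -1.30 to -2.07, the other 2 were so on 1 of 3 knockout arrays, and 3 of their probes name 1 shared sequence. Without that run and without pairs of 1 shared sequence, 25 pairs were left (permutation p = 0.0040), so shared sequence named in the files is not the whole cause; similarity that the files do not name was not tested. A regional difference between the edited line and the wild-type plants may remain.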
